A study of Mus musculus with 12 samples.

How the data were processed

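MLE-12 cells, a mouse line of lung epithelial origin, were used in 12 libraries, each the single member of its group. For the pull-down, per the labels' protocols, cells received 25 nM of biotinylated Mirlet7d, a microRNA of the let-7 family, were harvested after 48 h, and the RNA bound to it was captured on streptavidin beads and sequenced beside an input RNA library. ChIRP-seq is a method that captures chromatin through biotinylated probes against an RNA and sequences the attached DNA. Here 150 pmol of probes against mature Mirlet7d were used, per the labels' protocols, and an input library belongs to the same series. Processed tables of 2 samples, the pull-down and the ChIRP-seq, were analysed. The nuclear RNA-seq, small RNA-seq and PRO-seq libraries were not analysed here.

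The submitters' processing notes name FastQC, Trimmomatic, Bowtie2, SAMtools, Picard 1.119, HOMER and bedtools 2.15 for the pull-down, and FastQC, Bowtie2, SAMtools, bedtools, MACS and HOMER for ChIRP-seq, with genome mm9. Which step each tool carried out, and the versions of the transcript annotations, are not given in the labels. The pull-down tables hold RPKM values of input and pull-down, per the file headers, rounded by the authors to 3 decimals. The deposited fold is the quotient of pull-down and input RPKM, from which it differed by at most 0.005, and the lowest listed fold was 2.5, so the tables are selected lists. Folds given are this ratio as the authors deposited it. Length, as deposited, is the span from start to end with introns included, and coordinates are those of mm9. ChIRP-seq peaks carry the authors' deposited MACS score, whose lowest value was 30.01, and the deposited annotation gives a class, the distance to the nearest transcription start site (TSS) and the nearest gene. The score serves only to describe, rank or filter peaks within this list.

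Multiplied by length, the RPKM values of a column fell on whole multiples of one step, which is the worth of 1 read. Leaving out inputs of exactly 1, in each of the 4 columns 100% of the values with enough decimals lay within 0.15 reads of a whole number. The steps correspond to denominators of 23.9 M reads for the input and 42.0 M for the pull-down in the mRNA table, and 9.66 and 14.97 M in the ncRNA table. RPKM was therefore not compared between the mRNA and ncRNA tables. Where both read numbers could be recovered, a 95% exact interval of the fold was computed from them, with ncRNA reads counted as pairs because 80.7% of their input numbers were even. The interval covers counting error only, PCR copies are not separable, and it compares 2 libraries and not conditions. A single ncRNA input read was counted as 1 whole pair, so the interval then belongs to a ratio below the listed fold. An input of exactly 1 RPKM was left without an interval.

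Gene names were matched to a RefSeq gene table of assembly GRCm38.p6, used only for names, biotypes, gene length and chromosome. Of the names in the files, 2 of 1509 in the mRNA list, 1 of 1624 in the promoter-associated list and 3 of 3192 in the ChIRP-seq list found no match. In the promoter-associated list the accession of 25 names belongs to another current gene, often an antisense or neighbouring one. The deposited name was kept there unless the accession's gene carried it formerly, a rule set after the overlaps had been seen, and matching by accession first is among the alternatives. The background was the 26220 genes with a curated RefSeq transcript, of which 21031 are protein coding. It was not limited to genes expressed in these cells, so expression alone can give an excess in any overlap or list test.

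Gene overlaps were tested with Fisher's exact test, two-sided, and stratified by chromosome or by 1 Mb window of the gene start with the Mantel-Haenszel test, two-sided. Position was tested with 1000 circular shifts of the peaks within their chromosome, one-sided, over 20 chromosomes. Peaks per chromosome were tested with an exact binomial test against the chromosome's share of length, taken as the largest coordinate in the files, and chromosome Y was left out. The 16 gene lists were fixed before the data were examined and tested in 3 sets, with Benjamini-Hochberg adjustment over the 48 tests at 0.05. Shares carry exact Clopper-Pearson intervals. With 1 library per group there is no replicate check, and all p-values across genes or positions describe these libraries, since genes and peaks are not replicates. On simulated lists with no excess, Fisher's test over 26220 genes fell under 0.05 in 21 of 400 runs, after a shorter first run had been extended, and it found 100 added shared genes in 400 of 400. Without an excess the stratified test fell under 0.05 in 4 of 50 runs by chromosome and 3 of 50 by 1 Mb window, and the length-matched test in 3 of 50. The shift test fell under 0.05 in 2 of 20 runs with random peaks and in 20 of 20 with 10% of the peaks placed on targets. The simulated lists were drawn without regard to length, chromosome or region, and the simulated random peaks were not clustered as the real ones are. These runs therefore cannot show how well stratifying, matching or shifting removes such unevenness. Alternatives covered stricter peak and candidate sets, other backgrounds, lists matched on gene length in 20 bins, other windows and chromosomes. The planned tests of let-7 seed matches, of ncRNA candidates by gene name and of the promoter share by gene name were not run, because they need transcript sequences or gene names in the ncRNA table, which were not used here.

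Genes were named by a rule fixed before the data were examined. It took the 10 named entries with the highest fold per list, the 10 peaks with the highest score, the 10 shared genes with the highest peak score, up to 4 members of each gene list per set, and Mirlet7d, its cluster, Exosc10, C1d and Ezh2 wherever present. Any other gene named was chosen after its values were seen, whether or not this is repeated beside it. Some genes that meet the rule are not reported here. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.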

Results

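The 2 assays analysed ask which RNAs and which genomic sites associate with Mirlet7d in MLE-12 cells. Both have an input library in the series but no control capture. Enrichment therefore cannot separate association with Mirlet7d from capture without it. The pull-down gave 1964 mRNA transcripts of 1509 genes and 6208 ncRNA transcripts that merge into 4716 loci. Of the ncRNAs, 2432 at 1624 genes form a separate list of promoter-associated transcripts. ChIRP-seq gave 4286 peaks nearest to 3192 genes. Each library stood alone in its group, so no value below has a replicate error.

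Among the mRNA candidates the 10 highest folds belonged to 9 genes. Tcf7, which encodes a transcription factor of the WNT pathway, had a listed fold of 132 and Ap1s2, a subunit of a clathrin adaptor complex, 130.5. Tle6, a member of the Groucho family, was listed with 2 transcripts at 129.5 and 129.25. Tmem173, the innate immune adaptor STING, had a fold of 120.5, and the organic anion transporter Slco2b1 had 120. Mcee, an enzyme of methylmalonyl-CoA metabolism, reached 118.5. Wdr89, the nucleotide sugar transporter Slc35d2 and Card6 reached 114, 113 and 110. All of these rest on an input of 1 read, so their order is not settled. For Tcf7, Slco2b1, Wdr89 and Slc35d2, with an input of 0.001 RPKM, rounding alone can lower the fold to 87.7, 79.7, 75.7 and 75. For Ap1s2, with 224 reads in the pull-down, the interval ran from 22.6 to 5045, and for Tmem173, with 209, from 21.1 to 4708. The median fold of the list was 4.93, and 26.4% of the transcripts exceeded 10. The most abundant mRNAs, chosen after their values were seen, had far tighter folds. Eef2, the translation elongation factor, rose from 778 to 2874 RPKM (3.69-fold, interval 3.67 to 3.72). Ldha, lactate dehydrogenase A, had 14.1-fold (13.7 to 14.5).

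Members of the fixed lists were spread over the mRNA candidates. Among 45 let-7 target genes 4 were listed. Hmga2, a chromatin protein and textbook let-7 target, had a fold of 13. The collagen gene Col1a2 had 9.5, E2f6 3.73 and Acvr1c 2.83. For Hmga2 the input was 0.002 RPKM, and rounding alone can lower its fold to 10.2. The mesenchymal and extracellular matrix list had 6 of 33 members, led by Snai1 (57.8, interval 10.1 to 2287) and Pdgfrb (48), with 1.90 expected and an adjusted p of 0.0993 by Fisher's exact test. WNT signalling had Tcf7, Fzd4 (47.4, interval 27.2 to 92.5) and Wnt11 (7.75). The list of Polycomb repressive complex 2 and nuclear exosome had Exosc3 (9.07, 5.78 to 15.1), Mphosph6 (5.14) and Eed (2.98). From Pol II elongation came Ell3 (10.5), Leo1 (5.77) and Ell2 (4.21). TGF-beta and BMP signalling gave Ltbp1 (24.7), Acvr1b (3.01) and Ltbp2 (3.0). Lung epithelial markers gave Muc1 (24.2), Sox9 (5.68) and Lamp3 (3.3), and endothelial markers Tek (12) and Kdr (8.5). Imprinted genes were Plagl1 (5.24), Cdkn1c (3.95) and Nnat (2.61). Nhp2 (9.57) and Rrp9 (3.01) came from ribosome biogenesis, Prkra (3.13) from microRNA processing, Sos2 (3.01) from RAS signalling and Mrc1 (5) from immune markers. No cell cycle, Hox or let-7 gene was listed, and 0 of the 16 lists passed the adjusted threshold of 0.05 in this set. An interval could be computed for 924 transcripts and lay above 1 for 92.9% of them, but above the listing limit of 2.5 for 62.4%. Only folds of at least 2.5 from these same counts were listed, which favours intervals above 1. The share of 92.9% therefore cannot show that the folds are reliable. For 206 transcripts the rounding of RPKM alone could bring the fold under 2.5, among them Ltbp2 (1.67). The median input of the list was 0.014 RPKM, and 568 of the 1964 transcripts had at most 0.003. Among the list members above, Hmga2, Col1a2, Pdgfrb, Ltbp1, Ltbp2, Wnt11, Tek, Kdr and Mrc1 had inputs of 0.001 to 0.005 RPKM.

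Among the promoter-associated ncRNAs the transcript at Zfp605, a zinc finger gene, had a fold of 303 (interval 26.9 to 5991, 1 input read). Those at Ccnb1, which encodes the mitotic cyclin B1, 9930014A18Rik and the kinase gene Riok3 had 200.7, 192.75 and 169.6. Snord87, a small nucleolar RNA locus, had 169, the RNase P subunit gene Rpp30 had 154.6 and Abcf1 had 147.1. The BMP receptor gene Acvr1 had 140, Hnrnpa3, an RNA-binding protein, 131.05 (36.0 to 1083) and Samd10 128.3. The Acvr1 entry spans 168274 bases with an input of 0.001 RPKM, and rounding alone can lower its fold to 93. Hnrnpa3 had 4 input reads and the others with recovered reads 1 or 2, so the order of these entries is not settled. With 1 input read, as at Zfp605, the interval belongs to a ratio below the listed fold. The ncRNA with the highest fold of all, chosen after its value was seen, was NONMMUT050747 on chromosome 4 from 150377768 to 150378730 with 792.9 (71.1 to 15730), and it was not promoter associated. The highest level was at Malat1, a nuclear long non-coding RNA, with 2596 RPKM in the pull-down and 3.01-fold enrichment (2.81 to 3.23). Gas5, a small nucleolar RNA host gene, accounted for 20 transcripts and Mir6390 for 61.

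The promoter-associated list made up 39.2% of the ncRNA candidates (2432 of 6208, 95% interval 38.0 to 40.4%), every entry being shared by identifier. In 57 cases the TSS could be placed from the peak annotation, and the ncRNA reached to within 2372 bases of it in each. Against a background not limited to genes expressed in these cells, only the list of RNA polymerase II elongation and pausing passed the adjusted threshold. It had 8 of 30 members against 1.86 expected (odds ratio 5.53, 95% interval 2.61 to 12.7, adjusted p 0.00871 by Fisher's exact test). The ncRNAs at Paf1 (11.7-fold), Ell3 (5.0) and Supt16 (4.96) had the highest folds, and Ctr9, Med26, Hexim1 and Aff1 also belonged to the group. Paf1 and Ctr9 are subunits of the PAF elongation complex, and Hexim1 inhibits P-TEFb. The ncRNA at Ctr9 (4.53-fold) rests on 2 input and 14 pull-down reads, and its interval of 0.58 to 204 includes 1. With only the more enriched candidates the call ended (1 of 30, adjusted p 0.889), and the Polycomb and exosome genes passed instead (5 of 29, adjusted p 0.0288).

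Other lists in the promoter-associated set did not pass the adjusted threshold. WNT signalling had 6 of 33 (adjusted p 0.117), among them the destruction complex gene Axin2 (8.36), Dvl3 (6.88), Fzd6 (6.07) and Axin1 (3.19). Polycomb and exosome genes had 5 of 29 (adjusted p 0.17 by Fisher's exact test), with Rbbp4 (10.1), Phf19 (9.02), Ezh1 (7.84) and Rbm7 (6.25). TGF-beta and BMP signalling had 5 of 35 (0.25), with Acvr1 and Smad4 (78.5) highest, then Acvr2a (13.3) and Bmpr1a (7.52). The Acvr1 fold is open to the rounding given above, and Smad4 rests on 1 input read (interval 6.81 to 1580). Nnat (17.2), Igf2r (7.26), Gas5 (4.05) and Snhg3 (3.48) led the imprinted and long non-coding list, and Nat10 (19.4), Nhp2 (10.1), Rrn3 (6.46) and Polr1c (2.94) ribosome biogenesis. Ccnb1 and Bub1 (11.5) were the cell cycle members, Hoxa9 (5.79) and Hoxb2 (3.49) the Hox members, and Cd68 (24.5), Ago2 (19.4), Pik3cd (7.69) and Ctgf (5.02) the only members of their lists. None of the 45 let-7 targets, 32 lung epithelial markers, 18 endothelial markers or 13 let-7 genes was in this set. The folds of Nnat, Cd68, Rrn3, Hoxa9, Axin1, Bmpr1a and Hexim1 rest on an input of exactly 1 RPKM, which 1563 ncRNA candidates (25.2%) carry.

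Genes on both pull-down lists numbered 143, with 93.2 expected (odds ratio 1.65, 95% interval 1.38 to 1.98, p = 2.62e-07 by Fisher's exact test). In 115 of the 143 (80.4%) the spans of the ncRNA and the mRNA overlap, as at Ell3, Nhp2 and Nnat, so the same reads can stand in both lists.

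**Figure D1:**
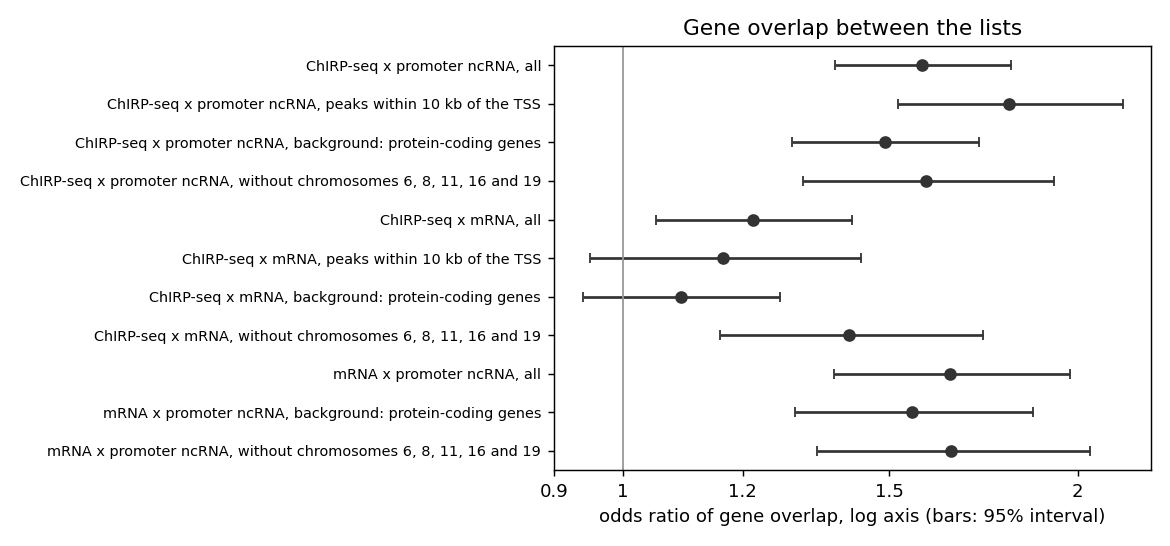
Odds ratios of the gene overlaps (points) with their 95% intervals (bars) on a log axis, for all entries and for other settings. The ChIRP-seq and promoter ncRNA overlap lies at 1.58 with all entries, and the ChIRP-seq and mRNA overlap at 1.22, reaching below 1 in its interval with protein-coding genes as background.

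The highest ChIRP-seq scores stood mostly outside genes, several of them on multi-copy sequence. The 2 peaks with the maximal score of 3100 lay on chromosome 1 from 24618236 to 24623365, nearest to Col19a1, and on chromosome 17 from 39979426 to 39985980, nearest to Esp38. A peak of 1328 on chromosome 6 (3150527 to 3152048, nearest to Gm8579) is annotated as small-subunit ribosomal RNA repeat, and one of 428.9 on chromosome 11 nearest to Axin2 as large-subunit ribosomal RNA repeat, 91609 bases from the TSS. The peaks nearest to Gad2 (1326) and 1700019M22Rik (469), Rn4.5s (329.7 and 317.9), Hsfy2 (286.65) and Nxph1 (260.1) complete the 10. Rn4.5s, a tandem array of a small RNA gene on chromosome 6, had 15 peaks. By class, 42.6% of the peaks were intronic, 40.0% intergenic and 9.45% at promoters (95% interval 8.59 to 10.4%). The median width was 646 bases, and 75.2% of the peaks had a score under 40 with a median of 34.3.

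Some genes of lung epithelium and of signalling pathways were the nearest genes to ChIRP-seq peaks. The background here too was not limited to expressed genes, and the lists were not matched on expression. Of the lung epithelial markers 11 of 32 had a peak against 3.89 expected (odds ratio 3.797, adjusted p 0.015 by Fisher's exact test). Sftpb, which encodes surfactant protein B, had a promoter peak with a score of 117.1 at a TSS distance of -255 bases. Etv5 had 89.4, Sox9 40.2 and Scgb1a1, a club cell marker, 38.1, at TSS distances of -1414, -6591 and 34839 bases. WNT signalling had 12 of 33 (4.14, adjusted p 0.00871), led by the Axin2 repeat peak, Tcf7l2 (77.2), Wnt7a (45.8) and Wnt5b (40.6), and PI3K, RAS and insulin signalling had 11 of 34 (3.47, adjusted p 0.0198), among them Insr (48.6) and Erbb2 (45.6). The PI3K call ended against lists matched on gene length (adjusted p 0.158), and the lung epithelial call with the higher-scoring peaks (7 of 32, adjusted p 0.0515), although its odds ratio was 3.96. Without the 5 chromosomes rich in peaks these 3 lists no longer passed. The odds ratio was 2.69 for lung epithelium (4 of 23, adjusted p 0.391) and 1.92 for PI3K (3 of 23, 0.731), but stayed at 3.93 for WNT, where fewer genes were left to test (4 of 17, 0.296), while TGF-beta and BMP signalling passed with 8 of 33 (0.0495). Stratified by chromosome all 3 passed, with 0.015, 0.0417 and 0.0282, as did TGF-beta and BMP signalling (0.015) and microRNA processing (0.0417). With peaks within 10 kb of the TSS, adjusted over the 16 lists, only the lung epithelial markers passed (8 of 32, adjusted p 0.00743).

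Members of further lists that did not pass the threshold were also nearest genes to peaks. They are linked at any distance, with TSS distances from -108 bases for Med1 to 180743 for Bach1. Of all peaks, 42.6% lay within 10 kb of a TSS. The let-7 targets had 8 of 45 (adjusted p 0.554), with Igf2bp3 (122.5), Ccnd1 (55.9), Insr and Bach1 (32.7) highest. Ezh1 (47.9), Exosc6 (49.5), Aebp2 (33.4) and Ezh2 (30.1) came from the Polycomb and exosome list, the Ezh2 peak at a TSS distance of -26347 bases. Mirlet7i was nearest to 1 peak of 33.9, at a TSS distance of -8923 bases. Mirlet7d, Mirlet7a-1, Mirlet7f-1, Exosc10 and C1d had no peak and no entry in the mRNA or promoter-associated lists. Ribosome biogenesis had Nolc1 (67.1, at the promoter), Nop2 (64.75), Rrp12 (58.55) and Nop56 (47.4). Skil (50.7), Smad3 (41.6), Ski (40.2) and Id3 (40.0) were the TGF-beta members with the highest scores, Drosha (43.5), Dgcr8 (34.65), Tnrc6c (33.4) and Ago4 (31.8) those of microRNA processing, and Vim (44.0), Snai1 (40.3), Col1a1 (38.2) and Col6a1 (36.25) those of the mesenchyme. Mcm2 (52.5), Ccnd1, Mcm5 (41.9) and Cdkn1b (36.2) were the cell cycle genes, Vwf (54.0), Pecam1 (47.9), Egfl7 (40.0) and Erg (32.4) the endothelial ones, and Hoxb7 (35.1) and Hoxb13 (31.2) were Hox genes. Peg10 (35.5), Malat1 (34.2), Ube3a (33.7) and Neat1 (33.65) were imprinted or long non-coding, Med1 (33.1), Aff1 (31.6), Med26 (31.5) and Cdk7 (30.05) belonged to Pol II elongation, and Klrb1c (34.6) to immune cells.

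Chromosomes 6, 8, 11, 16 and 19 held 62.2% of the peaks on 21.3% of the length. Their densities ran from 3.94 to 5.54 peaks per Mb, against 0.27 to 0.993 on the other 15. Each of the 5 exceeded its length share, from 2.42 times on chromosome 16 to 3.41 times on chromosome 19 (adjusted p 2.6e-54 and 2.82e-81, exact binomial test). Chromosome 11 had 61 peaks up to 70 Mb and 564 beyond, a boundary chosen after the data were seen. Candidate ncRNAs were 1.25 times as dense on the 5 chromosomes as on the others.

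**Figure D2:**
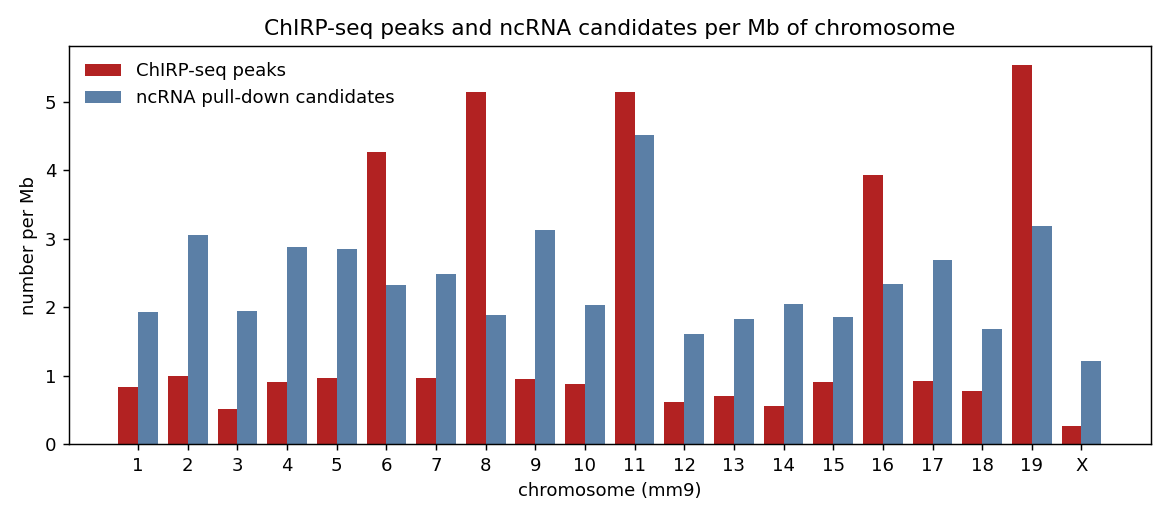
Bars give ChIRP-seq peaks and ncRNA pull-down candidates per Mb for each chromosome. Peaks reach 5.54 per Mb on chromosome 19 and stay under 1 on every chromosome outside 6, 8, 11, 16 and 19.

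**Figure D3:**
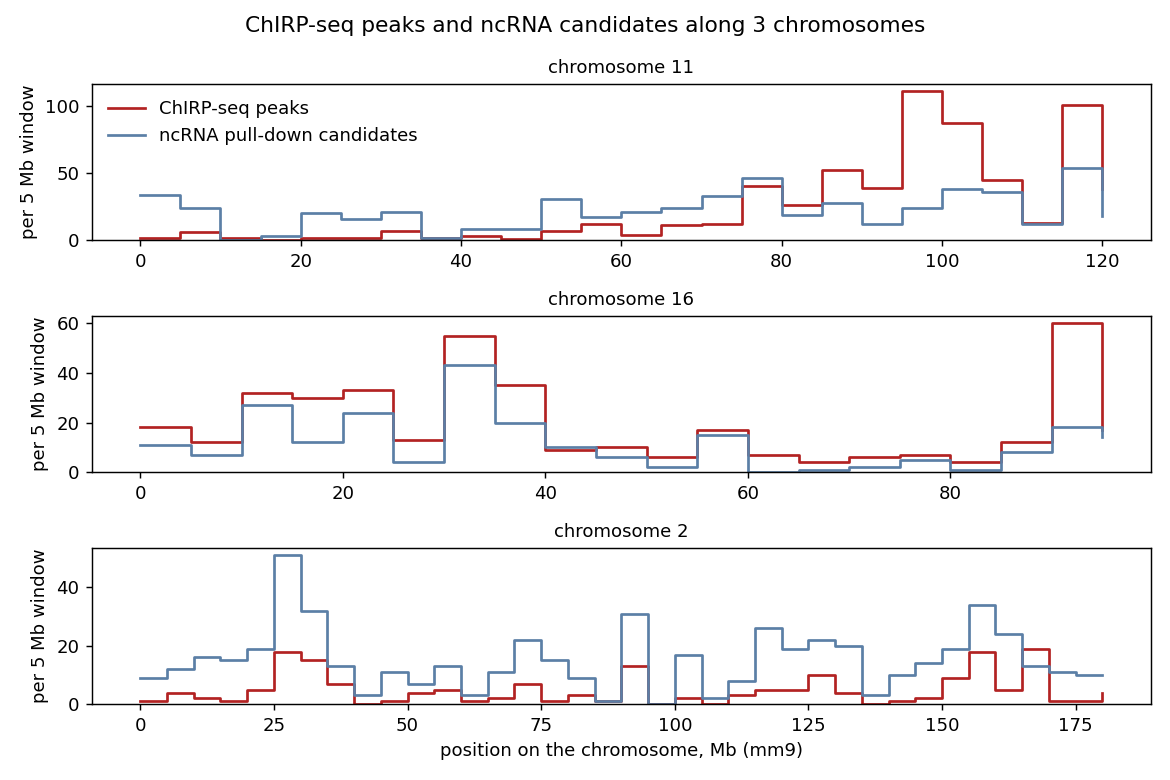
Lines give the number of ChIRP-seq peaks and ncRNA candidates per 5 Mb window along chromosomes 11, 16 and 2. On chromosome 11 the peaks rise beyond 70 Mb, where 564 of its 625 peaks lie.

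Genes nearest to ChIRP-seq peaks and genes with a pulled-down promoter ncRNA had 283 in common against 197 expected (odds ratio 1.58, 95% interval 1.38 to 1.81, p = 1.39e-10, Fisher's exact test). The 10 shared genes with the highest scores were Axin2, the peroxisome gene Pex2, Txndc11 (164.4), Nfkb2 (130.2), which encodes an NF-kappaB subunit, Neto1 (126.4), Prr15l (99.5), the small Maf factor gene Mafg (96.9), Abhd6 (96.8), Wbp1l (92.9) and Tbl1xr1 (92.5). The Nfkb2 peak lay 3 bases from the TSS and its ncRNA was enriched 5.21-fold, and the Mafg promoter peak went with 4.25-fold. By contrast the peaks at Axin2, Pex2, Txndc11 and Neto1 lie on ribosomal RNA repeats and that at Abhd6 on a telomere repeat. Those at Pex2, Tbl1xr1 and Neto1 have TSS distances of -284328, -378044 and -696879 bases. Without peaks on ribosomal RNA, simple, satellite and low-complexity repeats and at Rn4.5s, called multi-copy repeats here, the odds ratio was 1.55. Peaks on LINE, LTR and SINE repeats elsewhere were kept, as at Tbl1xr1, so repeated sequence was not removed as a whole. A promoter peak and a promoter ncRNA coincided at 51 genes, and 25 genes were in all 3 sets, among them Cnnm2, Dcun1d5 and Csgalnact1, chosen after their values were seen. For the overlap of ChIRP-seq and promoter ncRNA genes, the odds ratio was 1.49 with protein-coding genes as background. It was 1.47 without olfactory, vomeronasal and microRNA genes and 1.39 with the most enriched candidates. With the highest-scoring peaks it was 1.65, and with peaks within 10 kb of the TSS 1.80. With all 49997 genes that have a symbol as background the odds ratio was 3.31. Nearly all listed genes have a curated transcript, so this wider background raises the value by construction.

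By position, 532 of 4285 peaks (12.4%) lay within 10 kb of an ncRNA candidate, 2.47 times the mean of 215 over 1000 circular shifts (p = 0.001 by the permutation test of circular shifts, one-sided, the smallest the shifts can give). Peaks near mRNA candidates gave 1.69 over whole-chromosome shifts, against the 2.47 for ncRNA candidates. With shifts of at most 1 Mb, run only for ncRNA candidates, the ratio was 1.45. By gene, the peaks and mRNA candidates shared 215 genes against 183 expected (odds ratio 1.22, 95% interval 1.05 to 1.42, p = 0.0105 by Fisher's exact test), and the ratio to lists matched on gene length was 1.02 (p = 0.373, one-sided), so the excess did not hold once length was matched.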

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

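Of the tests weighed in this part, comparisons with chromosome length and gene number, matching on gene length and shifts within 1 Mb were planned. The choice of the 5 chromosomes, the ratios formed for them and the other tests came only after the results had been seen. ChIRP-seq peaks annotated as ribosomal RNA repeat numbered 36 and those on telomere repeats 23, read from annotation details that no planned comparison used. Of the 36, 18 were among the 100 peaks with the highest score, and their median score was 73.7 against 34.3 for all peaks.

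Peaks crowd onto chromosomes 6, 8, 11, 16 and 19. Chromosome length is argued against by the planned test over all chromosomes, where densities ran from 0.27 to 5.54 peaks per Mb. The 5 were picked for a density over 2 times the median, so their lowest ratio to the length share, 2.42, largely restates that choice. Gene density is argued against by 5.25 times as many peaks per gene there. Loci of pulled-down ncRNAs, the biological explanation tested, are argued against by their density ratio of 1.25. Extra copies of these chromosomes or segments may contribute, but the annotation classes cannot decide it. The 5 were picked by peak density, so high ratios in the large classes were mostly set by that choice. Intergenic peaks, the least affected class among those with at least 50 peaks, were 5.34 times as dense there. This shows only that the excess was not confined to promoters. Copy number was not measured, promoter peaks were denser still at 7.54 times, and higher transcription or open promoters on these chromosomes were not tested.

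Many ncRNA candidates share an input of exactly 1 RPKM. Only 29.7% of these inputs were a whole number of reads within 0.15, where chance gives 30% and the other inputs gave 100%, so a fixed value in place of the measured one is a likely source. Their folds are then not measured folds. No biological explanation was tested for this pattern.

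The overlap of ChIRP-seq genes with promoter ncRNA genes was not removed by gene length, chromosome or region, each taken alone. It was 1.36 times that of lists matched on gene length, and the odds ratio was 1.58 stratified by chromosome and 1.39 stratified by 1 Mb window. By position, peaks near ncRNA candidates of all kinds were 1.45 times those of shifts within 1 Mb against 2.47 over whole chromosomes, so broad regions may carry part of that excess. Open chromatin or transcription at the same promoters, and binding by Mirlet7d, both stay open, since neither a random-probe library nor expression values were used here.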

How the results depend on the processing

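Alternatives on backgrounds other than protein-coding genes, chromosomes, 1 Mb windows, multi-copy repeats, accession matching, overlapping spans, TSS distance for the gene lists, RPKM rounding, inputs of exactly 1 and loci were chosen after seeing the data. In all, 56 alternative values did not change materially. This means the same direction and side of the threshold for tests, a share within the main 95% interval, or a count within 1.5 times the main one. The 56 thus include list counts that went from 3 to 2 or stayed equal while another list passed. They also include values with all genes that have a symbol as background, which are raised by construction. The excess of mRNA candidates among ChIRP-seq genes (odds ratio 1.22) passed no threshold with the highest-scoring peaks (1.15), peaks within 10 kb of the TSS (1.17), protein-coding background (1.09), the most enriched candidates (1.06), a background without olfactory, vomeronasal and microRNA genes (1.121) or lists matched on length (1.02), and the cause was tested only for length. It kept its threshold without the 5 chromosomes (1.41), stratified by chromosome (1.28) or 1 Mb window (1.24) and without multi-copy repeats (1.23). The value of 2.55 with all genes that have a symbol as background is raised by construction and lends no support. The mRNA and ncRNA overlap turned to 0.324 when genes with overlapping spans were removed, which removes shared genes only and lowers the value by construction. The promoter share of ncRNAs was 41.2% by coordinates, that of peaks 11.4% among the highest scores and 13.8% within 1 kb of the TSS. Lists passing in the ChIRP-seq genes went from 3 to 1 without the 5 chromosomes, 1 within 10 kb of the TSS and 5 stratified by chromosome, but without the 5 chromosomes the WNT odds ratio stayed at 3.93 against 4.14. They were 2 with the higher-scoring peaks and 2 matched on length. In the ncRNA set the count stayed at 1 with the more enriched candidates, but the list passing was another one. The cause was not tested. A fold of at least 5 left 740 mRNA genes, 885 promoter ncRNA genes and 3139 ncRNAs. Seed matches and tests by gene name in the ncRNA list were not run. Low input reads limit the highest folds.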

Other observations

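The gene families in this part were chosen after the lists had been seen and tested on those same lists with Fisher's exact test. Benjamini-Hochberg adjustment over the 30 tests does not cover that choice. The background was not limited to genes expressed in these cells, and families were not matched on expression or length. An excess or a shortage below can therefore follow from expression alone, and the values only describe the lists. Ribosomal protein genes had a pulled-down promoter ncRNA at 15 of 81 members against 5.01 expected (odds ratio 3.47, adjusted p 0.000382), Rpl12 and Rps20 among them. Mitochondrial ribosomal protein genes had 12 of 78 (2.77, adjusted p 0.00639) and Snhg host genes of small nucleolar RNAs 5 of 17 (6.33, adjusted p 0.00639), namely Snhg3, Snhg5, Snhg8, Snhg14 and Snhg15. Among mRNA candidates solute carrier genes had 49 of 382 (2.46, adjusted p 9.81e-07). Zinc finger genes named Zfp were in excess in both pull-down sets, with 45 and 46 of 403 (odds ratios 2.1 and 1.98), but not in the ChIRP-seq genes, with 43 (0.862).

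Olfactory receptor genes were rare in every set, with 1, 0 and 11 of 1126 members. Runx1 had 9 peaks and Rhou 10, the highest numbers after the 15 of Rn4.5s.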
